A study of Mus musculus with 2 samples.

How the data were processed

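Single-cell RNA sequencing was done on lung immune cells of mice aged 6 to 8 weeks, 1 library from wild-type (WT) lung and 1 from knockout (KO) lung. The deposited values are raw counts of unique molecular identifiers (UMIs, tags that mark single RNA molecules) per gene and cell barcode, per the file headers. Per the labels, libraries were made with 10x Genomics Chromium Next GEM 3' chemistry, version 3.1, which reads the 3' end of each transcript. Per the submitters' processing notes, Cell Ranger 6.1.1 and the mouse build mm10/GRCm38 were used. The gene annotation and whether intronic reads were counted are not given in the sources used here. How immune cells were enriched, the number and sex of the mice per library, the strain and the gene knocked out are also not given in the sources used here. The 32285 gene identifiers were matched to GENCODE release M21 (GRCm38) for coordinates, and 32158 (99.6%) matched. Of the listed and marker genes, Aldoa and Ddit3 were not measured because 2 genes share the symbol, and Mx1 and Ly6a2 because the feature list does not hold them.

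Both deposited barcode sets held no barcode under 500 UMIs. Barcodes with under 300 genes or over 10% mitochondrial UMIs were removed. This took out 1218 WT and 394 KO barcodes. Over the mitochondrial ceiling were 1172 WT (13.3%) and 370 KO barcodes (3.95%), and under 300 genes 468 and 201, with 422 and 177 failing both. Doublets were called per library with Scrublet as carried in scanpy 1.11.5, at an expected rate of 8%. It marked 222 WT cells (2.92%) and 239 KO cells (2.66%), which were removed. There remained 7388 WT cells (83.7% of barcodes, median 12682.5 UMIs) and 8731 KO cells (93.2%, median 11726 UMIs).

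Cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled with values capped at 10, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1.0. Clusters that mixed classes were split again at resolution 0.5. Clusters were named from 26 marker lists: a name needed at least 3 detected markers. A cluster stayed unnamed if its 10 leading genes held more markers of another class than of its best one, which held for every unnamed cluster here, or if its UMI count was low and those genes held no marker of the name. Every class name is read as "-like". The rule that splits mixed clusters was written and revised after the clusters were seen. Cluster 7.7, 21 KO cells led by both Camp and Ccl5, stayed in the neutrophil class.

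With 1 library per genotype there is no replicate spread and no test, and no p-value was computed. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, sums of counts carry exact Poisson 95% intervals, and ratios carry exact 95% intervals on the split of a gene's counts given the library totals. All of these cover counting error only. A count of 0 was set to 3 counts for a bound. In each class with at least 100 cells in both libraries, counts were summed per library and scaled by the class total to counts per 1e6 (CPM). A gene was measured in a class if it reached 20 CPM in 1 library and 50 counts over both. It was called apart if the KO over WT ratio was at least 2 or at most 0.5 and its interval excluded 1. Own expression of a gene means that its level in the class, in the library where it was higher, was at least 0.25 times its highest level over all classes of at least 20 cells in that library. Genes failing this can be free RNA from other cells.

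Named genes followed a fixed rule: in a macrophage class the 12 genes with the largest and the 12 with the smallest ratio among those apart, and in another class the 3 largest and 3 smallest. Predicted, mitochondrial, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes and genes without own expression were left out of that ranking. Besides these, up to 4 members of each list with the largest absolute log2 ratio are named, and Ccl24, Ccr3, Tsc1 and Tsc2. Further names were chosen after their values were seen, and some genes that the rule names are not reported here. There were 25 gene lists, and each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these libraries only, and lists with fewer than 4 measured members are given per gene. Shares of cells with a UMI were also taken after thinning each cell to 2000 UMIs.

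The filters, markers, lists, statistics and most alternatives were chosen before the data were examined. These alternatives were no or a 5% mitochondrial ceiling, a minimum of 1000 UMIs, doublets kept, Leiden resolutions of 0.5 and 2.0, scaling within each library before clustering, clustering without the listed genes, scaling by the median of ratios, a mean over cells, and gene floors of 10 and 100 CPM. Chosen after seeing the data were shares of non-neutrophils, genes with own expression only, classes without named clusters, and each gene without the 1% of cells holding most of its counts. The doublet rate, the depth for thinning and the limit of 20 cells in the rule on own expression were also not fixed beforehand. The interstitial or monocyte-derived macrophage class was planned as a main comparison but held 15 WT cells, so no ratio was computed in it.

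The statistics were tested on simulated counts with the real means and totals of each class and about 200 changed genes. Among 6609 simulated genes of alveolar macrophages and 5917 of T cells, genes made 3-fold or 5-fold apart were called in 100% and no unchanged gene was called. Among 6172 genes of classical monocytes, 98.5% of 3-fold changes and 0.0839% of unchanged genes were called, and among 4481 genes of neutrophils 100% and 0%. A 1.5-fold change was called in 0% of alveolar macrophage and T cell genes, 6.35% of monocyte genes and 1.61% of neutrophil genes. Intervals held the true ratio for 95.1% of alveolar macrophage genes, 95.3% of T cell genes, 95.4% of monocyte genes and 95.4% of neutrophil genes. The simulated sums were Poisson draws, the same model that the intervals assume. They held no clumping of counts in few cells and no spread between libraries. These values thus check the computation and do not give the rate of wrong calls in the real libraries. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.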

Results

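The series addresses how mTORC1 signalling bears on the chemokine CCL24 and its receptor CCR3 in granuloma formation, and this part of it profiled single immune cells of WT and KO lung. The WT library held 8828 barcodes and 109019015 UMIs, with a median of 10118.5 UMIs and 3289.5 genes per barcode. The KO library held 9364 barcodes and 130148940 UMIs, with a median of 11500 UMIs and 2408 genes. With 1 library per genotype nothing below is a test of genotype: every value compares these libraries, and every interval covers counting error only. Xist, the X-inactivation transcript of females, was counted in both libraries, at 972 CPM in WT and 706 CPM in KO alveolar macrophages. A UMI of Xist was present in 99.6% of WT and 98.5% of KO alveolar macrophages. Of the 5 listed sex-linked genes, Xist was the only 1 measured in this class, so no listed Y-linked gene reached the floor there.

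The labels do not name the gene knocked out, so no targeted gene could be read as a check of the labels. Tsc1 and Tsc2 encode the complex that restrains mTORC1, and Lyz2 and Itgax are loci that commonly drive Cre recombinase in myeloid cells. Tsc1 (chromosome 2, 28641228 to 28691167) stood at 27.1 CPM (26.0 to 28.3) in WT and 22.5 CPM (19.7 to 25.6) in KO alveolar macrophages, and at 25.5 and 23.4 CPM in T cells. Tsc2 (chromosome 17, 24595816 to 24632630) stood at 12.8 CPM in WT and 15.2 CPM in KO alveolar macrophages. In the same cells Lyz2 had 7725 and 5555 CPM and Itgax 227 and 256 CPM. Counts from the 3' end of a transcript outside a deleted exon check nothing, so neither locus is shown to be intact or deleted.

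Alveolar macrophages, the resident macrophages of the airspace, made up 60.1% of WT cells (95% interval 59.0 to 61.2; 4442 of 7388) and 5.30% of KO cells (4.84 to 5.79; 463 of 8731), an 11.3-fold lower share. Neutrophils went the other way, from 6.47% (5.92 to 7.06; 478 cells) in WT to 67.4% (66.4 to 68.4; 5883 cells) in KO, a 10.4-fold higher share. Classical monocytes, the circulating Ly6c2-expressing precursors of macrophages, made up 1.41% (1.15 to 1.70) in WT and 12.1% (11.4 to 12.8) in KO. Interstitial or monocyte-derived macrophages made up 0.203% (0.114 to 0.335; 15 cells) in WT and 2.70% (2.37 to 3.07; 236 cells) in KO. Basophils numbered 3 in WT and 98 in KO.

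Lymphocytes held smaller shares of the KO library. T cells made up 17.6% (16.7 to 18.5) in WT and 7.86% (7.30 to 8.44) in KO, and B cells 4.52% (4.06 to 5.02) and 1.08% (0.871 to 1.32). NK cells numbered 300 in WT (4.06%, 3.62 to 4.54) and 3 in KO (0.0344%, 0.0071 to 0.100). The KO number rests on the clustering: with scaling within each library it was 38, against 299 in WT, and cluster 7.3, named T cell with 29 KO cells, was led by Gzma, Ccl5 and Nkg7. Nonclassical monocytes made up 2.08% in WT and 0.573% in KO. Conventional dendritic cells of type 1 numbered 46 and 1, and migratory dendritic cells 41 and 1. No cluster met the eosinophil markers, and Epx, which encodes eosinophil peroxidase, had 0 counts in WT and KO alveolar macrophages and in neutrophils of both libraries. Among cells that are not neutrophils (6910 WT, 2848 KO) alveolar macrophages still held a lower share in KO, 64.3% against 16.3%, while T cells turned to a higher one, 18.8% against 24.1%. Unnamed clusters held 1.48% and 0.996%. Over the alternative filters and clusterings, KO interstitial or monocyte-derived macrophages numbered 132 to 245, KO nonclassical monocytes 28 to 65, KO B cells 47 to 97 and WT conventional dendritic cells of type 1 20 to 48.

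**Figure D1:**
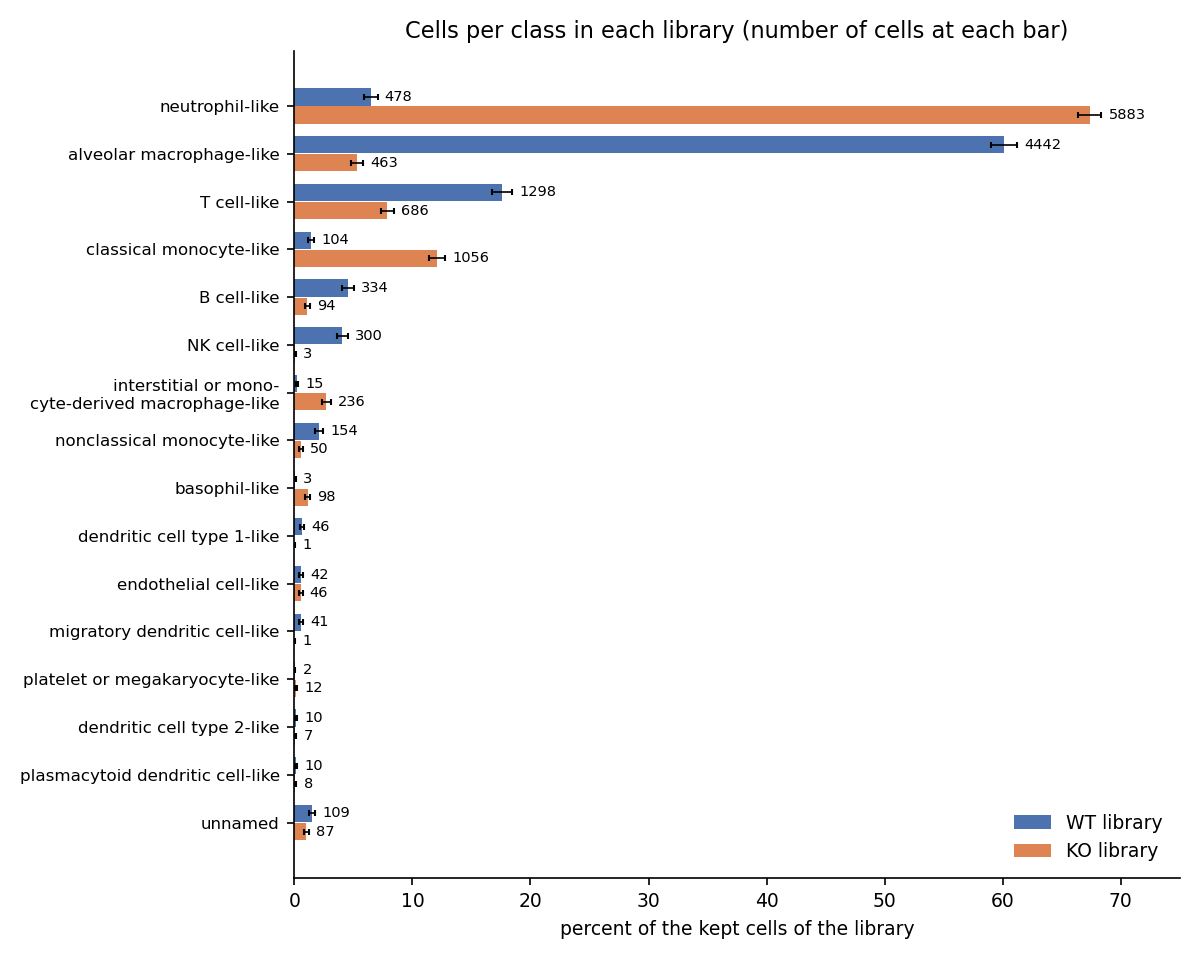
Percent of the kept cells of each library (horizontal axis) per cell class (vertical axis), with exact 95% binomial intervals as error bars and cell numbers at the bars. Alveolar macrophages filled 60.1% of the WT library and neutrophils 67.4% of the KO library.

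Most of these classes were made of different clusters in each library. Alveolar macrophages of WT lay in cluster 4 (49.6%), cluster 2 (30.7%) and cluster 3 (13.8%), and those of KO in cluster 18 (70.2%). WT neutrophils lay in cluster 0 (88.5%), and KO neutrophils in clusters 16 (30.1%), 21 (21.3%), 24 (20.4%), 23 (15.01%) and 25 (11.6%). WT T cells lay in clusters 12 (43.3%) and 1 (41.8%), both with Lef1 among their leading genes, and KO T cells in cluster 22 (53.5%). Clusters 14 and 17 held 98.1% and 1.92% of WT classical monocytes and 76.8% and 23.2% of KO ones. With 1 library per genotype, a cluster mostly of 1 library may be that library, not a type. The mitochondrial ceiling also removed unequal shares of barcodes, 13.3% of WT and 3.95% of KO.

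Ccl24, which encodes the CCR3 ligand eotaxin-2 (chromosome 5, 135569937 to 135573049, minus strand), was counted 3753 times in WT alveolar macrophages and 0 times in KO ones. That is 45.5 CPM (44.0 to 47.0) against less than the 0.288 CPM that 3 counts would give, at least 158-fold lower. The WT counts came from few cells: 27 of the 4442 (0.608%, 0.401 to 0.883) had 10 or more Ccl24 UMIs, and they held 3612 counts (96.2%). A count of 0 in 463 KO cells allows up to 0.648% of such cells, so a loss of them was not detectable at this cell number. The counting interval on the 3753 counts leaves out this clustering of counts in cells and is too narrow as an error of the level. Without the 1% of cells holding most of its counts, Ccl24 in WT alveolar macrophages stood at 1.34 CPM. At least 1 UMI was present in 3.47% of WT alveolar macrophages (154 cells, median depth 17692.5 UMIs) and 0% of KO ones (22129). After thinning to 2000 UMIs, which left out 3 cells in each library, the shares were 1.04% and 0%. As background, 2.08% of WT T cells (median depth 6307, 0.388% thinned, 11 cells left out) and 0% of KO T cells (11637, 14 left out) had a UMI. So did 1.497% of WT B cells (5205.5, 0.621% thinned, 12 left out) and 1.06% of KO B cells (13011, 1.08% thinned, 1 left out). Of the 154 WT alveolar macrophages with a UMI, 117 had exactly 1. The 4415 cells outside the 27 held 141 counts, 1.73 CPM, against 28 counts in the 8475202 UMIs of WT T cells. Ccl24 above background was thus not shown outside the 27 cells.

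The KO library held Ccl24 in another class. Its interstitial or monocyte-derived macrophages had 156 counts, 25.7 CPM (21.8 to 30.04), with a UMI in 27 of 236 cells (11.4%, median depth 25644.5; 0.87% thinned, 6 cells left out). In 3 of these cells 82 of the 156 counts (52.6%) lay, and without the 1% of cells with most counts the level was 12.4 CPM. It was 13.7 CPM with no mitochondrial ceiling, 15.2 at a minimum of 1000 UMIs and 30.8 at a mitochondrial ceiling of 5%. The 15 WT cells of that class had 4 counts in 2 cells, 18.1 CPM (4.93 to 46.3). KO classical monocytes had 43 counts, 1.51 CPM, with a UMI in 3.60% of cells (median depth 24683; 0.19% thinned, 5 cells left out). Ccr3 (chromosome 9, 124021972 to 124031689) was sparse. KO basophils had 12 counts, 10.1 CPM (5.20 to 17.6), with a UMI in 11.2% of cells (median depth 10547; 1.03% thinned, 1 cell left out), against 0.875% of KO T cells (0.149% thinned). WT neutrophils had 11 counts, 6.97 CPM, KO neutrophils 46 counts, 0.708 CPM, and WT alveolar macrophages 0. Of the CCR3 ligands besides Ccl24, Ccl5 was measured in alveolar macrophages, at 13.6 and 20.997 CPM, in both cases under its T cell level.

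**Figure D2:**
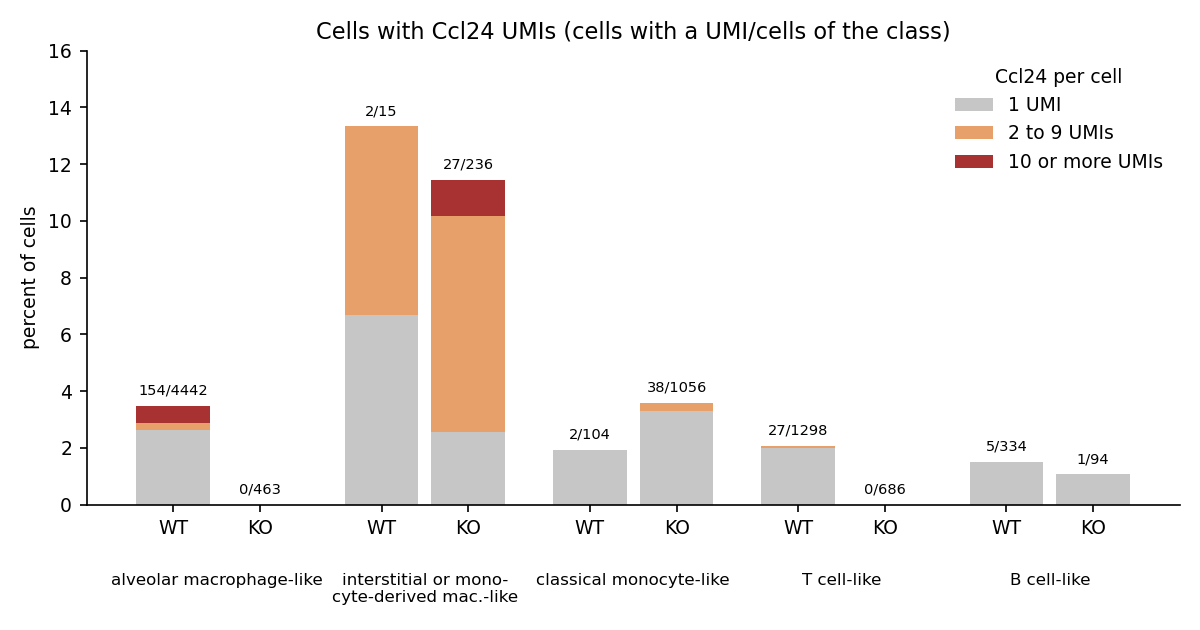
Percent of cells with Ccl24 UMIs (vertical axis) per class and library, split by Ccl24 UMIs per cell, with cells with a UMI over cells of the class written at each bar. WT alveolar macrophages had 154 of 4442 such cells, 27 of them with 10 or more UMIs, KO ones 0 of 463, and KO interstitial or monocyte-derived macrophages 27 of 236.

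KO alveolar macrophages stood higher in 7 of 13 measured dissociation and stress genes, such as Egr1, and in Ccl2, the monocyte-attracting chemokine. They stood lower in the matrix protease Mmp12, the gluconeogenic enzyme Fbp1 and the lipid carrier Fabp5. Most WT counts of Mmp12 and Fbp1 came from the 27 cells rich in Ccl24. Of 6826 measured genes 113 were at least 2-fold higher in KO and 61 at least 2-fold lower; with own expression only, 53 and 46. The sums behind this were 82528576 UMIs in WT and 10429977 in KO. Among the highest, Ccl2 had 1.27 CPM in WT and 26.7 in KO (log2 ratio 4.39, 4.06 to 4.73), Egr1, an immediate early transcription factor, 5.20 and 48.2 (3.21, 3.03 to 3.40), and the phosphatase gene Dusp1 82.6 and 454 (2.46, 2.41 to 2.51). Ch25h, cholesterol 25-hydroxylase, had 49.3 and 297 CPM (2.59, 2.53 to 2.66), and the costimulatory molecule Cd86 had 5.62 and 32.98 (2.55, 2.35 to 2.76). The others named among the highest were Eif3j2 (4.44), Plekha6 (4.16), the peptide transporter Slc15a2 (4.06), Gatm of creatine synthesis (3.20), Hspa1b (3.07) and Colec12 (2.47). Cd86 (36603869 to 36666081) and Slc15a2 (36750177 to 36784962) lie close together on chromosome 16. Gatm (chromosome 2, 122594467 to 122611303) lies near Eif3j1 and Stard9, which were lower. Whether the ratios of such neighbours share a cause was not tested. For Colec12, 61.6% of KO counts came from 10 cells. For Ccl2, 10 cells held 64.8% of the WT and 38.8% of the KO counts. The counting intervals leave out such clustering of counts in cells. Car1 was at least 952-fold higher, but its 361 KO counts all came from 1 cell. Egr1, Hspa1b and Dusp1 belong to the dissociation and stress list, and 70.2% of KO cells lay in cluster 18.

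Among the lowest besides Ccl24, Fbp1 (chromosome 13, 62864753 to 62888282) had 24.6 CPM in WT and 3 counts, 0.288 CPM, in KO (log2 ratio -6.42, -8.69 to -4.87). Mmp12, macrophage elastase (chromosome 9, 7344381 to 7369499), had 44.0 and 3.93 CPM (-3.48, -3.97 to -3.04). The 27 WT cells rich in Ccl24 held 77.3% of the WT counts of Fbp1 and 75.9% of those of Mmp12, and without these cells the log2 ratios were -4.30 (-6.58 to -2.74) and -1.45 (-1.94 to -0.997). The WT levels were then 5.66 and 10.7 CPM. Both genes thus lay under the floor of 20 CPM in both libraries and would not count as measured. Without the 1% of cells holding most counts of the gene, Mmp12 stood at -2.89. The same removal left 0 KO counts of Fbp1, and the bound from 3 counts then allows only that it was lower by at least 1.63 in log2. Also lower were Stard9 46.5 and 2.68 CPM (-4.11), the ribosomal protein gene Rpl29 518 and 67.0 (-2.95), the VEGF receptor gene Flt1 292 and 56.3 (-2.38, -2.50 to -2.26), the nuclear receptor gene Esrrg 103 and 29.4 (-1.81), and Fabp5 424 and 134 (-1.66, -1.73 to -1.58). Eif3j1 was lower (-2.23) where its paralog Eif3j2 was higher, and reads of such a pair can be counted for either gene. Nt5e (-2.14), Mamdc2 (-1.89) and Hr (-1.73) completed the set.

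**Figure D3:**
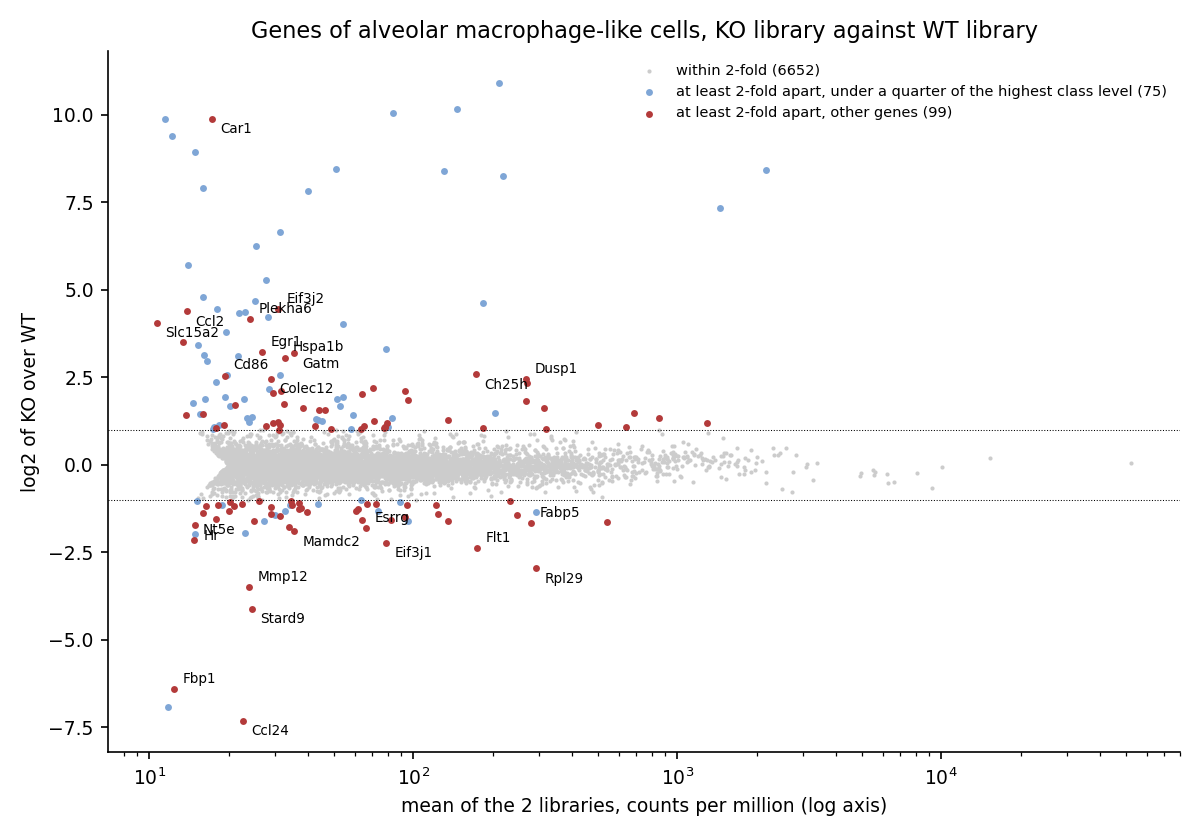
Each point is a measured gene of alveolar macrophages, with the mean of both libraries in CPM (horizontal axis, log scale) against the log2 of KO over WT (vertical axis). The 113 genes at least 2-fold higher include neutrophil transcripts such as S100a8, which can be free RNA, and Ccl24 is drawn at its bound.

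Neutrophil RNA was present in KO alveolar macrophages, classical monocytes and T cells and moved with the groups that follow. S100a8, an abundant neutrophil transcript, had 2889 CPM in KO alveolar macrophages against 17.9 in WT, 6802 against 5.33 in classical monocytes, and 3628 against 9.32 in T cells. In KO neutrophils it had 116181 CPM. Few cells carried much of these sums: 10 cells held 49.7% of the S100a8 counts of KO alveolar macrophages, 27.4% of those of classical monocytes and 62.6% of those of T cells. Without the 1% of cells with most S100a8 counts the log2 ratios were 7.01, 10.4 and 8.0002, and with doublets kept the T cell ratio was 3.295. A UMI of S100a8 was nonetheless present in 100% of KO alveolar macrophages and classical monocytes and in 99.9% of KO T cells. Over 12 neutrophil markers the median level, as percent of the KO neutrophil level, was 3.92 in KO alveolar macrophages and 5.98 in classical monocytes. It was 3.38 in T cells and 10.4 in B cells. The list of free RNA markers had a median log2 ratio of 3.88 in alveolar macrophages (S100a9 8.43, S100a8 7.33, Sftpc -1.98, Scgb1a1 0.44).

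By gene list, and leaving aside the free RNA markers, the dissociation and stress genes stood highest in KO alveolar macrophages: 7 of 13 measured members were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.07 (percentile 100 of matched random lists). Inflammatory activation genes had a median of 0.89 (percentile 100), with 0 of 6 at least 2-fold apart: the inflammasome gene Nlrp3 0.93, Il1b 0.89, Il1a 0.89 and Tnf 0.88. Granuloma and giant cell genes split, 2 of 11 higher and 2 lower around a median of 0.23 (percentile 99.3). The fatty acid receptor gene Cd36 had 153 and 471 CPM (1.62) and Apoe 14.5 and 143 CPM (3.30, without own expression), against Mmp12 and Fabp5 on the lower side. MHC class II presentation genes stood lowest, with a median of -1.06 (percentile 0): 4 of 7 lower, among them Cd74 420 and 165 CPM (-1.35), H2-Ab1 (-1.32) and H2-Eb1 (-1.13), none with own expression, and 1 higher, Cd86. Cholesterol synthesis genes had a median of -0.36 (percentile 0.03) with 0 of 13 apart, Fdps at -0.93, Pmvk at -0.62 and Idi1 at -0.60.

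Macrophage chemokines stood inside the random range (median -0.01): Ccl2, Ccl3 (4.03, without own expression) and Cxcl2 (2.05) were higher and Ccl24 lower, of 7. Lipid handling genes of alveolar macrophages were also inside it (0.09), with lipoprotein lipase Lpl (1.21) and the cholesterol exporter Abca1 (1.06) higher, Fabp1 (-1.64, also a naming marker) lower and Pparg at 0.90, of 14. Ribosomal proteins (0.21, percentile 100; 0 higher and 1 lower of 73), oxidative phosphorylation (0.04, 99.4; 0 of 76), the cell cycle (0.22, 99.3; 0 of 11) and hypoxia response (0.20, 97.7; 0 of 6) stood above the range with small medians. The cell cycle and hypoxia medians fell back inside it under several alternatives, for example 0.09 and 0.10 at a minimum of 1000 UMIs. Alternative activation (0.18), interferon response (0.03), glycolysis (-0.02), fatty acid synthesis (0.04; Scd2 1.14 higher), the ATF4 amino acid response (-0.01) and the lysosome (0.08; 0 of 24 apart) lay inside it. Of the eosinophil and type 2 list, Siglecf was measured, at 96.0 and 113 CPM.

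**Figure D4:**
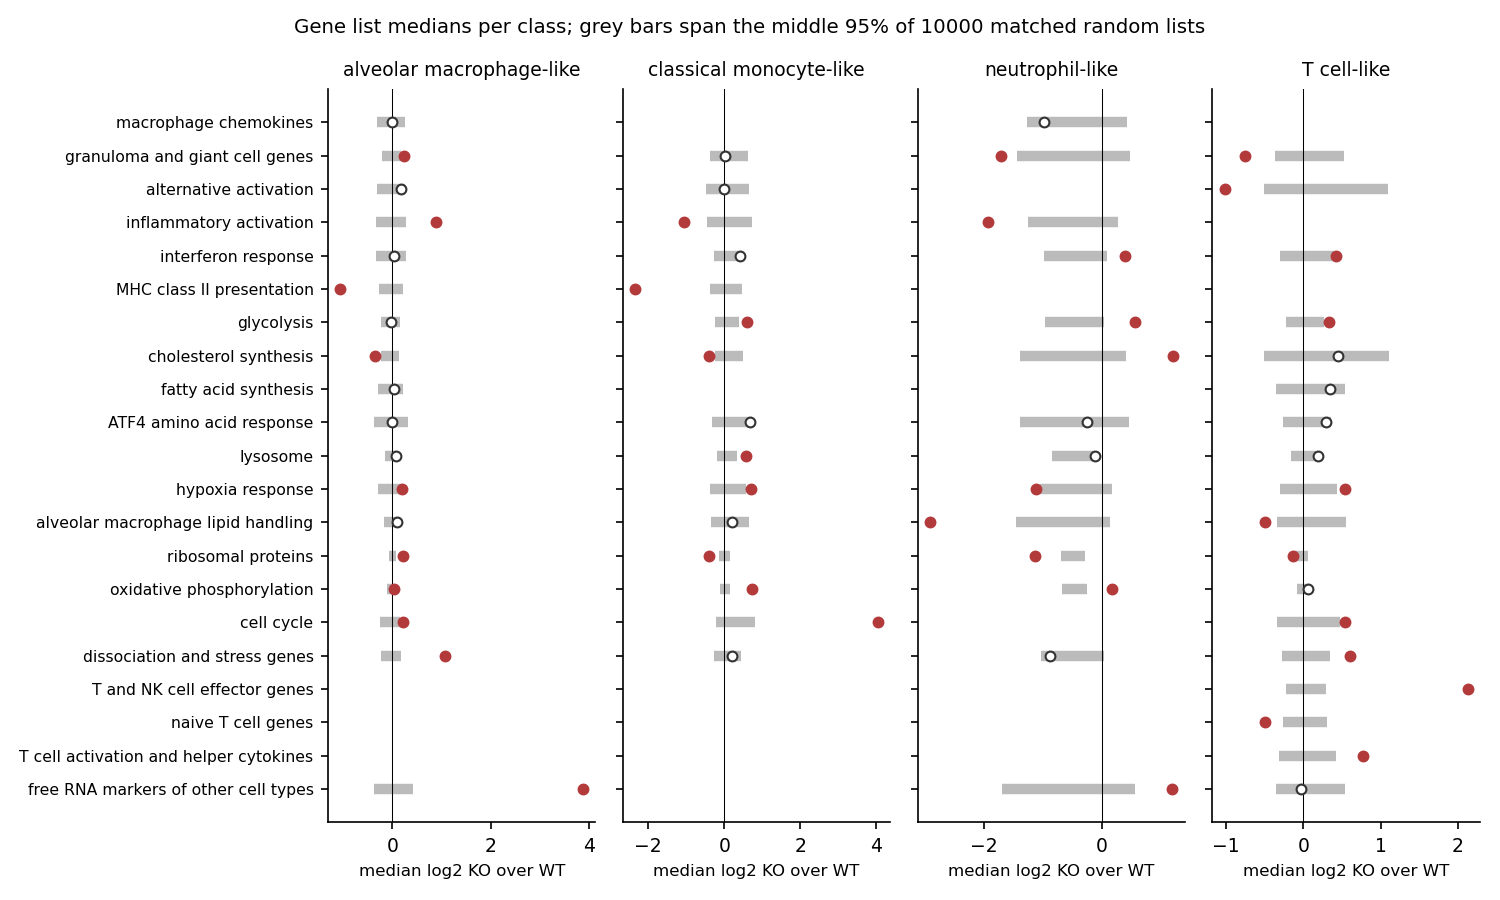
Median log2 ratio of KO over WT (horizontal axis) per gene list (vertical axis) in each compared class, with grey bars spanning the middle 95% of 10000 matched random lists. MHC class II genes lay below their bar in alveolar macrophages (-1.06) and classical monocytes (-2.35), and T and NK effector genes above it in T cells (2.13).

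Classical monocytes of the KO library carried more cell cycle and less MHC class II RNA than the 104 WT cells. All 17 measured cell cycle genes were at least 2-fold higher (median 4.05, percentile 100), among them Ccna2 (5.91), Birc5 (5.52) and Stmn1 (4.83). These 3 genes had a UMI in 0.962%, 1.92% and 6.73% of the 104 WT cells, so few WT counts stand behind their ratios. Cell cycle genes such as Top2a and Mki67 are among the leading genes of cluster 17, as is Prtn3. This cluster was treated as progenitor-like and held 245 KO cells (23.2%) and 2 WT cells. The class may thus not hold mature monocytes alone. Without that cluster the median of the list was 2.33 (percentile 99.6). Of 8 MHC class II genes 7 were lower (median -2.35, percentile 0): H2-Eb1 2378 and 215 CPM (-3.47, -3.53 to -3.40), H2-Ab1 (-3.25), H2-Aa (-3.14) and Cd74 (-2.71). Oxidative phosphorylation stood higher (0.73; 20 of 75 higher), as did glycolysis (0.61; 5 of 14, with Pgam1 1.21, Ldha 1.13, Pgk1 1.06 and Gapdh 1.05), the lysosome (0.57; 4 of 23, with Npc1 1.22) and hypoxia response (0.70; 1 of 5, Mif 1.03), which was inside the range without cluster 17 (0.499) and at a floor of 10 CPM (0.703). Among interferon response genes 5 of 11 were higher, led by the guanylate-binding proteins Gbp2 (3.32) and Gbp5 (3.30), with a median of 0.41 inside the range. That median lay above it under 4 alternatives: without cluster 17 (0.626), with a mean over cells (0.597) and at floors of 10 CPM (0.915) and 100 CPM (1.128).

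Inflammatory activation genes were lower in KO monocytes (median -1.06, percentile 0.005), 3 of 5: Il1b 141 and 20.01 CPM (-2.82), Cd14 (-1.35) and Il18 (-1.06), with the acute-phase gene Saa3 higher (3.93); none of these had own expression. Cholesterol synthesis (-0.41; 0 of 10) and ribosomal proteins (-0.39; 0 higher and 2 lower of 73) stood below the range. The granuloma genes (0.03), alternative activation (0.00), lipid handling (0.20), the ATF4 response (0.69) and stress genes (0.20) lay inside it, the ATF4 median above it with no mitochondrial ceiling (0.747) and with scaling within each library (0.782). Of 6479 measured genes 514 were higher and 242 lower; with own expression only, 408 and 148. The largest ratios were Prc1 (6.08, 3.60 to 11.39), Cdca3 (6.05) and Gpx3 (6.01), each on 1 WT count; the smallest were the chemokine receptor gene Cx3cr1, 212 and 13.1 CPM (-4.02, -4.26 to -3.78), Rnaset2b (-3.98) and Rpl29 (-3.75). The WT sum was 1125956 UMIs against 28489691.

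Neutrophils of the KO library were higher in cholesterol synthesis genes and lower in inflammatory and ribosomal protein genes. Median depth was 3178.5 UMIs in WT and 9748 in KO cells. The median of all 4811 measured genes was -0.50, so list values are read beside it. Cholesterol synthesis had a median of 1.20 (percentile 99.9), 5 of 7 higher, with Srebf2 at 1.72 and Hmgcs1 at 1.63. Glycolysis had 0.56 (percentile 100): Pgam1 (1.70), Hk2 (1.48) and Ldha (1.14) were higher and Slc2a1 (-1.62) lower, of 13. Oxidative phosphorylation (0.17; 4 higher and 2 lower of 65) and interferon response (0.39; 3 higher and 1 lower of 12, with Ifi47 2.11) also stood above the range, the interferon median not at a floor of 100 CPM (0.188).

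On the lower side, 5 of 6 inflammatory activation genes were lower (median -1.92, percentile 0.04): Il1b 2207 and 382 CPM (-2.53, -2.58 to -2.48), Nlrp3 (-2.31), Cd14 (-2.26) and Ptgs2 (-1.59). Of 74 ribosomal protein genes 47 were lower and 1 higher (-1.13, percentile 0), and of 9 hypoxia genes 5 were lower and 1 higher (-1.12), with Ndrg1 at -2.46 and Hif1a at -1.81. The hypoxia median was inside the range without the clusters led by Camp, Ltf and Ngp (-0.52), with a mean over cells (-0.753) and with scaling within each library (-0.868). Lipid handling (-2.92; 8 of 11 lower; -1.47 and inside the range at a floor of 100 CPM) and granuloma genes (-1.70; 3 of 6 lower and 1 higher) were lower too. The members that led these lists, Fabp1 (-6.17) and Spp1 (-3.40), had no own expression in neutrophils and are abundant in WT alveolar macrophages. Stress genes (-0.88; 6 of 12 lower), chemokines (-0.97; 2 of 5 lower, Ccl4 at -3.31), the lysosome (-0.12) and the ATF4 response (-0.26) lay inside the range. With scaling within each library the chemokine median was 0.84, above it. The lysosome median lay above it under 4 alternatives, from -0.123 when clustered without the listed genes to 0.0135 without the clusters led by Camp, Ltf and Ngp.

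In all, 335 genes of neutrophils were higher and 1210 lower; with own expression only, 273 and 911. Scaling by the median of ratios gave 660 higher and 556 lower, so the excess of lower genes rests on the scaling. Mgst2 (5.63) and Mapk7 (5.46), each on 1 WT count, and H2-Q6 (5.21, on 4) were the highest, and Arhgap31 (-6.99), Ccdc80 (-6.11) and the interleukin-8 receptor gene Cxcr1 (-5.07) the lowest.

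T cells of the KO library were higher in effector genes and lower in genes of naive cells. Of 11 effector genes 7 were higher (median 2.13, percentile 100): the chemokine Ccl5 806 and 6929 CPM (3.104, 3.07 to 3.14), the interleukin-2 receptor gene Il2rb (3.002), Cxcr3 (2.83) and the granzyme gene Gzmk (2.47). Of 9 naive cell genes 4 were lower (-0.50, percentile 0.01): Dapl1 561 and 81.4 CPM (-2.79), Lef1 (-1.41), Ccr7 (-1.33) and Il7r (-1.03). Lef1 is also a naming marker, and Lef1, Dapl1 and Il7r are among the 10 leading genes of clusters 1 and 12, as Ccl5 leads cluster 22. Among activation genes Ctla4 (1.59) and Maf (1.17) were higher of 4 (median 0.77, percentile 99.8). These differences followed the clusters: without clusters 1 and 12, which held most WT cells, 194 WT and 635 KO cells remained, and the medians were -0.19 (effector, percentile 39.2), -0.03 (naive, 77.7) and -0.98 (activation, 0.02).

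Stress genes stood at 0.60 in T cells (2 of 7 higher: Dusp1 2.08 and Hsp90aa1 1.58), the cell cycle at 0.54 (0 of 4), hypoxia at 0.54 (1 higher and 1 lower of 6), interferon response at 0.42 (0 of 7) and glycolysis at 0.34 (0 of 11), all above the range. Without clusters 1 and 12 the stress (0.0421), cell cycle (0.016) and glycolysis (0.053) medians also lay inside it, and fatty acid synthesis (0.574) lay above it. The interferon median was inside it under 4 alternatives, for example 0.275 at a floor of 10 CPM. Glycolysis was inside it with a mean over cells (0.257) and at a floor of 100 CPM (0.114), and the cell cycle with a mean over cells (0.413) and with scaling within each library (0.3603). Alternative activation (-1.02), granuloma (-0.75) and lipid handling genes (-0.50) stood below it, led by the macrophage transcripts Mrc1 (-2.83), Cd9 (-1.93) and Fabp1 (-5.43) without own expression in T cells. The lipid handling median was inside the range with a mean over cells (-0.267) and with doublets kept (-0.304). Ribosomal proteins stood at -0.13 (percentile 0.455), inside the range at a floor of 100 CPM (-0.135, percentile 23.5) and at 0.31 without clusters 1 and 12. Oxidative phosphorylation (0.06), cholesterol synthesis (0.45), fatty acid synthesis (0.34), the ATF4 response (0.29) and the lysosome (0.19) lay inside it. Oxidative phosphorylation lay above it at a floor of 100 CPM (0.112), with no mitochondrial ceiling (0.102) and with doublets kept (0.108), and the lysosome with doublets kept (0.267). Of 6261 measured genes 376 were higher and 156 lower; with own expression only, 248 and 109. The desmosomal gene Dsg2 was at least 83.3-fold higher (0 and 248 counts), with Cpne4 (6.05, 4.48 to 8.34) on 3 WT counts and Dlg5 (5.77) next. Tmem108 (-6.47, -9.53 to -4.60) on 2 KO counts, the surfactant gene Sftpc (-4.93), a transcript of alveolar type 2 cells for which no class was named, and Auts2 (-4.07) were the lowest.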

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

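All comparisons in this part were chosen after the result was seen. In each, the list median of KO over WT lay above the random range in alveolar macrophages and below it in another class, or the reverse, and the difference between classes was not tested, since there is 1 library per genotype. Values are the alveolar macrophage median minus the other class's, in log2. Each median covers the members measured in that class, so the compared medians rest on partly different genes. For example, 11 granuloma genes were measured in alveolar macrophages, 5 in T cells and 6 in neutrophils. A difference can therefore come from which members were measured, and is not shown for the same genes. Granuloma and giant cell genes differed by 0.98 from T cells and by 1.93 from neutrophils. Inflammatory activation genes differed by 1.95 from classical monocytes, where none of the measured members had own expression, and by 2.81 from neutrophils. Ribosomal protein genes differed by 0.35 from T cells, 0.61 from classical monocytes and 1.35 from neutrophils. Without the naive clusters the T cell ribosomal median was 0.31, above the 0.21 of alveolar macrophages, so that difference turned its direction. Hypoxia response genes differed by 1.32 from neutrophils, but the alveolar macrophage median lay inside the random range under 8 alternatives and the neutrophil median under 3, so this contrast rests on the settings. Cholesterol synthesis genes, lower in alveolar macrophages and higher in neutrophils, differed by -1.56. The neutrophil medians stand beside an all-gene median of -0.50, and the T cell medians of the granuloma list are led by genes without own expression there.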

How the results depend on the processing

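Among the alternatives below, shares among non-neutrophils, own expression only, classes without named clusters and genes without the top 1% of cells were chosen after the result was seen. No paired analysis was possible because there was 1 library per genotype, and no replicate could be left out for the same reason. The interstitial or monocyte-derived macrophage class had no ratio under any setting. Over all settings, 65 share ratios stayed within their interval, 14 moved and 1 reversed. Counts of genes higher in KO stayed within 1.5 times in 47 cases and moved in 10, and so did counts of lower genes. Log2 ratios of named genes stayed in 3005 cases, moved in 389 and reversed in 14. List medians kept their place in 766 cases, came to lie inside the random range in 36, outside it in 21, and reversed in 2.

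With clustering without the listed genes, Ccl24 in KO interstitial or monocyte-derived macrophages was 30.1 CPM, and in alveolar macrophages the cell cycle median was 0.15 and hypoxia 0.18. With doublets kept, Ccl24 in WT alveolar macrophages was 42.8 CPM, the T cell log2 ratios of Cd74 (0.0437) and Lyz2 (0.051) reversed, and in alveolar macrophages the cell cycle was 0.15 and hypoxia 0.17. At a minimum of 1000 UMIs KO interstitial or monocyte-derived Ccl24 was 15.2 CPM, cell cycle 0.0857 and hypoxia 0.10. With a mitochondrial ceiling of 5% these were 30.8 CPM, 0.11 and 0.17, WT alveolar macrophage Ccl24 was 37.1 CPM and the neutrophil share ratio 9.44. With no mitochondrial ceiling KO interstitial or monocyte-derived Ccl24 was 13.7 CPM, the alveolar macrophage share ratio 0.102 and alveolar macrophage Ccl5 reversed (-0.11). With scaling within each library that Ccl24 was 30.4 CPM, neutrophil Ccl3 (1.38), Ccl4 (0.84) and Cxcl2 (1.501) reversed, and alveolar macrophage hypoxia was 0.12.

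At a floor of 10 CPM 182 genes were higher and 93 lower in alveolar macrophages, 852 and 366 in classical monocytes, 267 lower in T cells, and alveolar macrophage hypoxia was 0.0727. At a floor of 100 CPM the numbers were 35 and 18 in alveolar macrophages, 126 and 78 in classical monocytes, 114 and 511 in neutrophils and 107 and 37 in T cells, and alveolar macrophage lipid handling was 0.20, above the range. With own expression only, 248 genes were higher in T cells, 53 higher in alveolar macrophages and 148 lower in classical monocytes. With the median of ratios, 660 were higher and 556 lower in neutrophils, and neutrophil Chil3 (0.37), Itgax (0.0273) and Satb1 (0.0893) reversed. With a mean over cells, WT alveolar macrophage Ccl24 was 23.2 CPM, neutrophil Itgax (0.13) and T cell Stmn1 (-0.0736) reversed, and in alveolar macrophages hypoxia (0.11) and oxidative phosphorylation (0.0147) fell inside the range while lysosome (0.10) and chemokines (0.31) lay outside it.

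Among non-neutrophils the T cell share ratio reversed to 1.28 and the alveolar macrophage ratio was 0.253. Without the top 1% of cells per gene, Ccl24 was 12.4 CPM in KO interstitial or monocyte-derived and 1.34 CPM in WT alveolar macrophages, and classical monocyte Satb1 (0.04997), neutrophil Scgb1a1 (0.14) and T cell Stmn1 (-0.0182) reversed. Without the cycling cluster alveolar macrophage hypoxia was 0.0937. Without the naive clusters 181 genes were higher and 287 lower in T cells, and the activation (-0.98) and ribosomal (0.31) medians reversed.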

Other observations

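All tests in this part were chosen after the result was seen, except the test on colder handling. The 27 WT alveolar macrophages with 10 or more Ccl24 UMIs carried a set of other genes at far higher levels than the remaining 4415 cells. Arg1, arginase 1, had 538 CPM in them and 0.662 in the others, the chemokine Ccl17 873 and 3.34, Mmp12 2706 and 10.7, Fbp1 1538 and 5.66, and the ribonuclease gene Rnase2a 1009 and 3.53. These cells held 91.0% of the class counts of Arg1 and 76.6% of those of Ccl17. Chil3, a chitinase-like protein of alveolar macrophages, was 6.39-fold higher in them, Mrc1 was at 2010 and 2158 CPM, and Fabp1 (76.6 and 832) and Marco (63.8 and 527) were lower. All 27 lay in cluster 2, and their median depth was 35721 UMIs against 17649. Before doublets were removed, 27 WT cells had as many Ccl24 UMIs and 0 of them were called doublets, which does not exclude doublets that Scrublet missed. The genes were picked by their contrast in these same cells, so they describe these cells and are not independent evidence of a type.

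Interstitial or monocyte-derived macrophages of the KO library (236 cells) split on the granuloma and giant cell genes against KO alveolar macrophages. Of 9 members compared, leaving out class markers, 5 were at least 2-fold higher and 4 lower. Higher were Ocstamp at 21.1 CPM and 0 counts, Gpnmb 903 and 256 CPM, Fabp5 928 and 134, Acp5, an osteoclast phosphatase, 358 and 91.9, and Lgals3 3635 and 1552. Lower were Spp1, osteopontin, at 15.6 and 197 CPM, Cd9 at 89.4 and 2740, Ctsk at 34.4 and 302, and Cd36 at 47.7 and 471. Of 10 macrophage chemokines compared, 5 were higher, among them Ccl4 at 324 CPM against 7.48, and 2 lower, Ccl6 at 865 against 2784 and Cxcl14 at 1.98 against 34.0. Of 9 MHC class II genes 8 were higher and 0 lower, with Cd74 at 6236 against 165. Gpnmb, Cd74, H2-Eb1 and H2-Aa are among the leading genes of clusters 13.2 (139 KO cells) and 13.3 (88). Their higher level is thus in part built in by the clustering. Cluster 13.2 was named on a narrow margin, with a marker score of 2.92 against 2.78 for classical monocyte. The 15 WT cells of the class gave 221 CPM for Gpnmb, 280 for Fabp5, 560 for Spp1 and 5897 for Cd74, too few cells for a ratio. KO basophils, 98 cells, held the highest level of Ccr3 in that library among classes with at least 20 cells, 10.1 CPM.

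The neutrophil share was 6.47% in WT and 67.4% in KO. Removal of WT neutrophils by the cell filters is argued against: with all 1440 removed WT barcodes taken as neutrophils the WT share would be 21.7%, against 62.8% in KO with none added. This covers the deposited barcodes only, which held at least 500 UMIs. WT neutrophils were shallow (median 3178.5 UMIs against 9748 in KO), and a loss of them before that cut cannot be seen here. Loss of alveolar macrophages alone, with other cells in WT proportions, is argued against by neutrophils per T cell, which were 23.3-fold higher in KO (20.4 to 26.6). Another difference between the libraries, such as blood left in the tissue, infection or dissociation, and the genotype cannot be told apart with 1 library per genotype.

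Ccl24 had 0 counts in KO alveolar macrophages. A KO library that hides the transcript is argued against by its 156 counts (at least 132) in another KO class. Too few KO alveolar macrophages to catch the cells that carry it stays open as a candidate explanation: such cells were 0.608% of the WT class, and 0 of 463 allows 0.648%. At the WT frequency 2.81 such cells would be expected in KO. An effect of the genotype also stays open and was not tested.

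Of 3494 genes measured in all 4 compared classes, 10 were at least 2-fold higher in KO in each and 3 lower. The 10 were Camp, Lcn2, Ltf, Ly6c2, Ly6g, Ngp, Rbm3, S100a6, S100a8 and S100a9, and the 3 were Eif3j1, Fabp1 and Rpl29. Camp, Lcn2, Ltf, Ngp, S100a8 and S100a9 lead KO neutrophil clusters, so in the other classes they can be neutrophil RNA. Fabp1 is a naming marker of alveolar macrophages. A separate count took genes apart the same way with own expression in at least 3 classes, whether or not apart in the other one: 6 were higher (Eif3j2, Got1, Kif13b, Ly6c2, Rbm3, Slc15a2) and 3 lower (Eif3j1, Ocel1, Rpl29). A single segment of another strain beside the modified locus is argued against as the cause of all these 9. Each lay on a different chromosome, with at most 1 gene on any 1 of them. The places of these 9 genes alone cannot speak to several segments or to a strain difference between the libraries. Some named genes lay close together, as seen after their values were known. On chromosome 2 these were Stard9 (start 120629121), Eif3j1 (122028546) and Gatm (122594467), lower, lower and higher in KO alveolar macrophages. On chromosome 16 they were Cd86 (36603869) and Slc15a2 (36750177), both higher there. Closeness was not compared with that of all measured genes, and the strain is not given. Several segments or a strain difference thus stay open. Reads of Eif3j1 and Eif3j2 counted for the other paralog may account for part of that pair's pattern. Their summed CPM lay within 2-fold in 3 of 4 classes (median log2 ratio -0.56). The sum was still lower in KO in all 4, from -0.19 (-0.35 to -0.03) in T cells to -2.16 (-2.47 to -1.83) in neutrophils. Swapped counting alone would leave the sum unchanged. Colder handling of the KO tissue, which raises Rbm3 and Cirbp, cannot be told apart from other causes, with Cirbp at least 2-fold higher in 1 of 4 classes (median log2 ratio 0.72). In T cells Cirbp stood at -0.11 (-0.34 to 0.13), although Rbm3 stood at 1.28 there. In classical monocytes (0.98, 0.34 to 1.69) and neutrophils (0.46, -0.03 to 1.008) the Cirbp intervals reach past 2-fold, so these classes do not decide.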
